A study of Rattus norvegicus with 6 samples.

How the data were processed

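RNA was sequenced from cultured oligodendrocyte lineage cells of SD rats, in 3 libraries of precursors and 3 libraries of differentiated cells. Per the labels' protocols, precursors were grown in Raff medium, differentiation followed a change of growth factors, RNA was extracted with ISOGEN, and libraries were made with a stranded total RNA kit from Illumina. Per the submitters' processing notes, the tools used before deposit were bcl2fastq 2.20.0, Trimmomatic 0.38, HISAT2 2.1.0 and StringTie 2.1.3b. The same notes name the genome build GRCh38, which is a human assembly, whereas the deposited table identifies its genes by rat gene identifiers. The rat build, the annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes cannot be told apart with certainty and no coordinates are printed.

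The authors deposited 1 table for the whole series with 37991 genes, each with an identifier, a symbol and a biotype. For each library it holds a read count, an FPKM and a TPM. The deposited read counts are whole numbers that are not normalized, and their totals differ between libraries. The deposited FPKM values, which scale fragments by transcript length and library size, were made by the authors and were not used here. The deposited TPM values, which scale transcripts to a fixed total per library, were made by the authors. No column of the table belonged to a sample outside the series. A reference table of the assembly GRCr8 was used for names alone, and 29216 of the gene identifiers matched it. The symbols of 428 entries were shared with another entry, and such entries were told apart by their identifiers.

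Total counts per library ran from 55522101 to 79898629, a 1.44-fold range, so that a level of 1 CPM (counts scaled to a fixed library total) rested on 55.5 reads in the smallest library. A small noncoding RNA, the signal recognition particle RNA Rn7sl1, took 5.93% to 12.5% of the counts and 24.0% to 38.8% of the TPM of a library. Levels are therefore given as CPM scaled by the trimmed mean of M values (TMM). In 115 cases a gene had a count of 0 in 1 library while each of the other 5 libraries had at least 20 reads, so a single 0 in this table can be a failed estimate.

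Groups were taken from the sample labels. The comparison was differentiated against precursor cells, 3 against 3, with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low-count filter of that package, robust estimation) and limma 3.58.1 in R 4.3.3. Of all genes, 17797 passed the filter. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called when its adjusted p was under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Every adjusted p of a single gene below comes from this test unless another is named. The labels do not say that the replicates are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

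The sample titles number the replicates 1, 2 and 5 in both groups. Whether the numbers pair the samples was checked on the deviations of log2 CPM from the group means. Same-numbered libraries deviated together, with correlations across genes of 0.421 for number 1, 0.197 for number 2 and 0.272 for number 5. Each was above 0.1 and above every correlation between different numbers, the highest of which was 0.105 (precursor 5 with differentiated 2). The check is weak, since deviations within a group sum to 0. A deviation shared by the replicate 1 libraries alone thus raises the correlations among replicates 2 and 5. The numbers were taken to pair the samples, which the labels do not state, and a fit with the replicate number as a block is given beside results that it changes.

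Lists of genes were fixed before the data were examined, 30 in all: markers of oligodendrocyte precursors, of committed and of myelinating oligodendrocytes, lineage transcription factors, inhibitors of differentiation, lipid synthesis (cholesterol, fatty acids, galactolipids and sphingolipids), cell cycle (mitosis, DNA replication, histones, inhibitors of cyclin-dependent kinases), signalling and stress (growth factor and ERK targets, immediate early genes, p53 targets, endoplasmic reticulum (ER) stress, thyroid hormone and interferon responses), metabolism and translation (glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins), receptors and ion channels, and markers of astrocytes, microglia, neurons, fibroblasts and pericytes, endothelium, and Schwann, choroid or ependymal cells. Each was tested with camera of limma, which asks whether its genes moved relative to the other genes, at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry. List p-values were adjusted over the 30 lists. Members were also counted with p-values adjusted over the list alone. Cdkn2d and Ly6c had no match in the table, and Lhfpl3 was matched through the reference to the symbol LOC103692025.

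The genes named below follow a rule fixed before the data were examined. It takes the 12 genes of each direction with the largest fold change among called genes that moved the same way in each same-numbered pair and reached a mean of 5 TPM in the higher group, leaving out provisional symbols. It adds up to 4 members per list by smallest p and 15 lineage and cell type markers chosen in advance, and genes named outside the rule are said to be so.

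The test was tried on simulated counts for 17797 genes made from the precursor means, dispersions and library sizes of this comparison, with 100 genes of more than 20 expected reads changed per fold size. It called 22% of the genes changed 2-fold and 68% of those changed 4-fold, with median errors of -0.02 on the log2 scale for each size. Of its calls, 3.2% were unchanged genes, and camera called 0 of 20 unchanged lists. The simulated genes were drawn independently of each other and without a replicate effect. These results therefore do not cover genes that vary together, and cannot show how often camera calls unchanged lists in the real data. Far fewer genes were changed in the simulation than were called in the real data, which makes the adjustment of p-values stricter. The shares of changed genes called may therefore be lower than in the real comparison. The alternatives tried were the replicate block, each library left out in turn, the libraries with a day in their title alone, no or a stricter low-count filter, DESeq2 size factors, library size alone as scaling, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1), voom with sample quality weights, and the most abundant genes left out. The fit without both replicate 1 libraries and the list test with an estimated correlation under the block were chosen after seeing the data.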

Results

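Libraries of differentiated oligodendrocyte cultures differed from those of precursor cultures in genes of the myelin sheath, of lipid synthesis and of cell division, among others. The names differentiated cells and precursors stand for these groups of libraries. Each library holds RNA of a whole culture, in which genes of other cell types were also expressed. Changed shares of cells, changed expression within cells and effects of the changed growth factors therefore cannot be told apart. Transcripts of myelin proteins and of enzymes that make cholesterol, fatty acids and galactolipids were higher in differentiated cells. Transcripts of mitosis and of DNA replication were lower, and markers of astrocytes were higher in the differentiated libraries. The calls of the mitosis, DNA replication, fatty acid and astrocyte lists were lost with an estimated correlation between genes (camera adjusted p = 0.0642, 0.112, 0.0642 and 0.12), and those of myelin, cholesterol and galactolipids when the replicate block was added to it (0.15, 0.0992 and 0.141). These tests rest on few residual degrees of freedom, fewest with the block, so a lost call cannot show that a list did not move. The precursor marker Pdgfra did not pass the test over all libraries. Genes were tested with edgeR's quasi-likelihood method on 3 against 3 libraries. P-values measure the spread between these samples only, since the labels do not say whether replicates are separate cultures, and replicate 1 of both groups stood apart from the other replicates.

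The data are read counts of genes in 6 RNA libraries from cultured rat cells of the oligodendrocyte lineage, the cells that form myelin. Oligodendrocyte precursors made up 3 libraries and cells after differentiation the other 3, with replicate numbers 1, 2 and 5 in each group. The titles place replicates 1 and 2 at day 0 and day 3, and give no day in the same form for replicate 5. Total counts were 64800561, 68104279 and 63781754 for precursors 1, 2 and 5, and 79898629, 67022982 and 55522101 for differentiated 1, 2 and 5. Correlations of log2 CPM between libraries of a group were at least 0.946 for precursors and at least 0.953 for differentiated cells. The first principal component held 43.4% of the variance and the second 25.3%. On the second, both replicate 1 libraries lay apart at 41.8 (precursor) and 73.5 (differentiated), while the other libraries lay between -55.9 and -3.6.

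The comparison asks which messenger RNAs differ between the control condition, precursors before differentiation, and the differentiated condition. Mbp (24547), which encodes myelin basic protein, rose from 535 ± 306 CPM (SD, n = 3) in precursors to 8975 ± 1400 CPM in differentiated cells (log2 fold change 4.07, SE 0.41, edgeR adjusted p = 0.00166). Mag (29409) rose from 51.2 ± 24.7 to 997 ± 151 CPM (log2 fold change 4.28, SE 0.36, edgeR adjusted p = 0.000785). Mog (24558), a late myelin gene, rose from 1.72 ± 0.216 to 74.4 ± 3.37 CPM (log2 fold change 5.43, SE 0.15, edgeR adjusted p = 3.37e-05). Cnp (25275) rose from 593 ± 115 to 3718 ± 589 CPM, a log2 fold change of 2.65. Ugt8 (50555), the enzyme of galactocerebroside synthesis, rose from 97.6 ± 4.14 to 802 ± 38.5 CPM. Ccna2 (114494), a cyclin, fell from 98.5 ± 6.37 to 44.4 ± 2.27 CPM (log2 fold change -1.15, SE 0.11, edgeR adjusted p = 0.0012). Mki67 (291234), a marker of dividing cells, fell from 95.4 ± 23 to 41.7 ± 3.87 CPM (log2 fold change -1.19, edgeR adjusted p = 0.00886, and 0.0569 without differentiated 2). Pdgfra (25267), the receptor that marks precursors, was at 427 ± 85.6 CPM in precursors and 365 ± 4.79 CPM in differentiated cells, which did not pass the test (log2 fold change -0.23, SE 0.16, edgeR adjusted p = 0.45, lower in 2 of 3 same-numbered pairs). Without both replicate 1 libraries its log2 fold change was -0.38 at an edgeR adjusted p of 0.0341. Each gene said here or below to rise or fall moved that way in 3 of 3 same-numbered pairs.

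**Figure D1:**
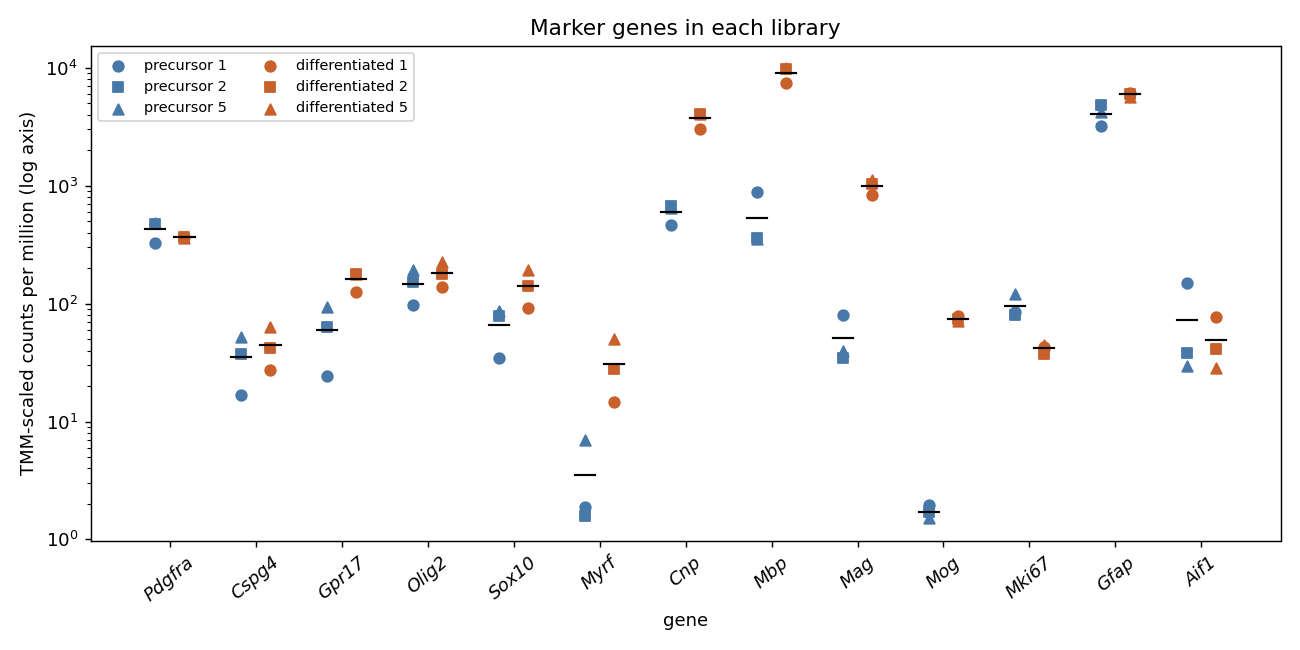
Levels of 13 marker genes in TMM-scaled CPM on a log axis, with a point per library (shape gives the replicate, colour the group) and a bar at each group mean. Mbp, Mag and Mog lay higher in each of the 3 differentiated libraries than in any precursor library, while Pdgfra, Cspg4, Gpr17, Olig2, Sox10, Gfap and Aif1 did not pass the test without the replicate block. With the block, Cspg4, Gpr17, Olig2, Sox10 and Gfap passed as higher (edgeR adjusted p from 0.00077 for Sox10 to 0.0479 for Cspg4), and Pdgfra and Aif1 did not pass.

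Of 17797 genes tested, 1005 were higher and 571 lower in differentiated cells at an edgeR adjusted p under 0.05, and 4110 had an unadjusted p under 0.05. Of these calls, 621 were at least 2-fold higher and 261 at least 2-fold lower, and 1516 were protein coding. With the replicate number as a block, 2643 genes were higher and 2797 lower, and 1565 of the 1576 genes called without it were among them with the same direction. Without both replicate 1 libraries, a choice made after seeing the data, the counts were 1546 higher and 1475 lower. The counts depended on single libraries. They were 511 higher and 165 lower without precursor 2, 639 and 266 without precursor 5, 456 and 162 without differentiated 2, and 504 and 174 without differentiated 5. The counts at least 2-fold lower were 109, 153, 119 and 116 in the same 4 fits, and those at least 2-fold higher were 394 without differentiated 2 and 411 without differentiated 5. Of the 1576 genes, 553 were called in each of the 6 leave-one-out fits, and 0 changed sign in any. The share of higher genes among calls, 63.8%, depended on the fit, the libraries and the scaling. It was 48.6% with the block, 51.2% without both replicate 1 libraries and 75.6% without precursor 2. With library size alone as the scaling it was 40.3%, and by limma-trend on log2(TPM + 1), which changes the test as well, 32.8%. The median log2 fold change over all tested genes was -0.188 and -0.172 with library size alone and on the TPM scale, and -0.038 with TMM scaling without the block. Among called genes, 13 had 0 counts in all precursor libraries and 13 had 0 counts in all differentiated libraries.

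Myelin and mature oligodendrocyte markers formed the list with the largest shift. Of 34 tested, 23 rose and 1 fell over all genes, and 27 rose and 3 fell adjusted over the list alone. Their median log2 fold change was 2.65 (camera adjusted p = 7.11e-52, and 0.0275 with an estimated correlation). With an estimated correlation under the replicate block, a test chosen after seeing the data, camera called none of the 30 lists, and the adjusted p of this list was 0.15. Few residual degrees of freedom are left under that block, so this test cannot show that the list did not move. With the block, 4 members fell, and without replicate 1, 29 rose and 4 fell. The 1 member that fell, Anln (363031), is a gene of cytokinesis that the mitosis list also holds, and was looked up after its value was seen. Its call was lost without precursor 2, without differentiated 2 and without differentiated 5, when 0 members of the list fell, while 2 fell without differentiated 1. Mobp (25037) rose from 2.38 to 124 CPM, a log2 fold change of 5.71 with SE 0.68. Pllp (64364) rose from 23.9 to 151 CPM, Gjb1 (29584) to 26.9 CPM at a log2 fold change of 3.16 and Adamts4 (66015) from 22.7 to 125 CPM.

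Markers of committed and newly formed oligodendrocytes were also higher. Of 20 tested, 13 rose over all genes and 16 adjusted over the list alone, and 0 fell (median log2 fold change 1.63, camera adjusted p = 6.74e-27, and 0.0642 with an estimated correlation). Nfasc (116690) rose from 56.4 to 653 CPM, Rras2 (365355) from 39.8 to 284 CPM, Enpp6 (306460) from 12.8 to 136 CPM and Kif19 (303659) from 19.2 to 67.4 CPM. Gpr17 (767613), a receptor of the committed stage, was at 60.1 ± 34.4 CPM in precursors and 161 ± 30.3 CPM in differentiated cells, with an edgeR adjusted p of 0.0985 (0.00603 with the block and 0.0454 without precursor 1, log2 fold change 1.42, higher in 3 of 3 pairs). Nkx2-2 (366214) had a log2 fold change of 0.21 and did not pass the test (edgeR adjusted p = 0.869, SE 0.54), and its fold change was -0.19 without precursor 1 and -0.10 without differentiated 5.

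Genes of lipid synthesis were higher in differentiated cells in each of 3 lists. Of 24 cholesterol synthesis genes, 15 rose over all genes and 18 adjusted over the list alone (median log2 fold change 0.59, camera adjusted p = 1.05e-10, and 0.0275 with an estimated correlation). Of 16 fatty acid synthesis genes, 12 rose and 15 adjusted over the list alone (median 1.10, camera adjusted p = 2.62e-17, and 0.0642 with an estimated correlation). Among 15 galactolipid and sphingolipid genes, 8 rose and 2 fell both over all genes and adjusted over the list alone (median 0.48, camera adjusted p = 4.13e-09, and 0.0287 with an estimated correlation). With an estimated correlation under the replicate block, the camera adjusted p was 0.0992 for cholesterol, 0.241 for fatty acid and 0.141 for galactolipid genes, so that these calls were lost. That test rests on few residual degrees of freedom and cannot show that these lists did not move. Scd2 (83792) rose from 3182 to 8478 CPM, Acsl3 (114024) from 221 to 551 CPM, Srebf1 (78968) from 150.0 to 332 CPM and Acss2 (311569) from 149 to 408 CPM. Cyp51 (25427) rose from 463 to 863 CPM, Sc5d (114100) from 129 to 265 CPM, Tm7sf2 (293688) from 68.6 to 192 CPM and Insig1 (64194) from 265 to 462 CPM. Gal3st1 (683713), the sulfatide enzyme, rose from 24.5 to 77.7 CPM, Cers2 (310667) from 107 to 239 CPM and Elovl7 (361895) from 2.12 to 9.31 CPM. The 2 members that fell were Cers4 (304208, log2 fold change -0.63) and Smpd3 (94338, -0.81), named after their values were seen. Neither was called without precursor 2, precursor 5, differentiated 2 or differentiated 5, when 0 members of that list fell, and 1 fell without differentiated 1. The number of galactolipid genes that rose was 5 without precursor 2, without differentiated 2 and without differentiated 5. The cholesterol count was 7 without precursor 2, 7 without precursor 5, 4 without differentiated 2 and 9 without differentiated 5, and the fatty acid count did not go below 8 in these fits. By limma on the TPM scale, 3 cholesterol, 7 fatty acid and 5 galactolipid genes rose, and 1 galactolipid gene fell. With DESeq2, 17, 14 and 8 rose, and 2 galactolipid genes fell.

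Genes of cell division were lower. All 28 called genes of 32 mitosis genes fell, and 32 of 32 fell adjusted over the list alone (median log2 fold change -0.83, camera adjusted p = 5.79e-27, and 0.0642 with an estimated correlation). Of 32 DNA replication genes, 23 fell and 31 fell adjusted over the list alone (median -0.70, camera adjusted p = 4.34e-17, and 0.112 with an estimated correlation). Cenpe (362044) fell by 1.34 on the log2 scale, Ndc80 (301701) by 1.05 and Kif11 (171304) fell by 0.97. Tyms (29261) fell from 55.4 to 29.5 CPM, Mcm4 (29728) from 166 to 98.4 CPM, Uhrf1 (316129) from 114 to 68.9 CPM and Pola1 (85241) from 56.4 to 32.8 CPM. The mitosis count was 16 without precursor 2 and 15 without differentiated 2 or differentiated 5. The replication count was 7 without precursor 2, 12 without precursor 5, 15 without differentiated 1, 8 without differentiated 2 and 7 without differentiated 5. Of 34 histone genes expressed with replication, 4 fell, and 15 fell adjusted over the list alone (median -0.41, camera adjusted p = 1.05e-05, and 0.429 with an estimated correlation). With the block 23 of them fell. The histone count was 2 without precursor 1, 6 without precursor 5 and 0 without any other single library, and Hist1h1b (680522) and Hist1h3a (679994), at log2 fold changes of -0.60 and -0.54, were among the 4. The list of inhibitors of cyclin-dependent kinases had 9 members tested, not all of them such inhibitors, since it also holds Rb1, Rbl1 and Rbl2. Of these members, 1 rose over all genes, while adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.868, median 0.08, which was negative with library size alone and on the TPM scale). The member that fell was Rbl1 (680111, log2 fold change -0.90, edgeR adjusted p = 0.0786 over all genes), not a kinase inhibitor gene. Cdkn1c (246060) rose from 33.4 to 110 CPM. Cdkn1a (114851) was at 68.1 and 57.8 CPM and did not pass the test (log2 fold change -0.23, edgeR adjusted p = 0.252).

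Precursor markers did not move together. Of 27, 5 rose and 0 fell over all genes, while adjusted over the list alone 5 rose and 1 fell. With the block 10 rose and 5 fell, and without replicate 1, 7 rose and 3 fell. Their median log2 fold change was 0.03 and their mean 0.33 (camera adjusted p = 0.0159, and 0.716 with an estimated correlation), and the median was -0.12 with library size alone and -0.15 on the TPM scale. That call was lost without precursor 1 (camera adjusted p = 0.284) and without differentiated 5 (0.057). Emid1 (685462) rose from 3.36 to 34.1 CPM, Gpr37l1 (252939) from 162 to 424 CPM, Scrg1 (64458) from 43.4 to 103 CPM and Kcnip3 (65199) from 22.4 to 41.6 CPM. Cspg4 (81651) did not pass the test at a log2 fold change of 0.32 (edgeR adjusted p = 0.734, 0.0479 with the block, higher in 3 of 3 pairs), and its fold change was -0.03 without precursor 1 or differentiated 5.

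Of 20 lineage transcription factors, 5 rose and 0 fell, both over all genes and adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 5.5e-05, and 0.413 with an estimated correlation). With the block 10 rose and 1 fell. Nkx6-2 (309095) rose from 3.99 to 42.5 CPM, St18 (266680) from 1.03 to 9.92 CPM, Zfp536 (292820) from 5.03 to 27.6 CPM and Zfp488 (290571) from 9.08 to 37.5 CPM. Myrf (293736), the myelin regulatory factor, rose from 3.49 ± 3.03 to 30.7 ± 17.7 CPM (log2 fold change 3.13, SE 0.70, edgeR adjusted p = 0.0348). Its call was lost without precursor 1, precursor 2, differentiated 2 or differentiated 5, with an edgeR adjusted p of up to 0.118. Sox10 (29361) and Olig2 (304103) had log2 fold changes of 1.10 and 0.30 and passed with the block, each higher in 3 of 3 pairs (edgeR adjusted p = 0.14 and 0.574 without the block, 0.00077 and 0.0182 with it). Of 22 inhibitors of oligodendrocyte differentiation, 2 rose and 2 fell over all genes, 3 and 3 adjusted over the list alone, and 5 and 6 with the block (camera adjusted p = 0.864). That list's median was -0.04, while its mean of 0.14 and its test pointed up. Hes5 (79225) rose from 3.92 to 16.9 CPM and Tmem108 (300967) from 5.36 to 21.4 CPM. Sox11 (84046) and E2f1 (399489) fell by 0.70 and fell by 0.55 on the log2 scale, and both calls were lost in each leave-one-out fit but that without precursor 1, with an edgeR adjusted p of up to 0.153 for Sox11 and 0.127 for E2f1.

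Genes outside these groups were among those with the largest changes under the fixed naming rule. Defb20 (641641) had 0 reads in each precursor library and 281, 86 and 103 reads in differentiated 1, 2 and 5, at least 164-fold higher against 3 counts over the precursor group. Col11a2 (294279) rose from 4.29 to 116 CPM, Kndc1 (361672) from 12.2 to 204 CPM and Gjc3 (288529), a connexin gene, from 5.15 to 136 CPM. Cyp3a9 (171352) rose from 0.687 to 13.8 CPM and Kcne4 (367302) from 0.947 to 15.9 CPM. Tmem151a is listed under 2 identifiers with nearly the same reads, 309158 and 108348045 (log2 fold changes 3.95 and 3.83), so its level is uncertain. Penk (29237), the proenkephalin gene, fell from 77.2 ± 5.72 to 8.77 ± 1.56 CPM (log2 fold change -3.14, SE 0.17, edgeR adjusted p = 0.000216). Aqp5 (25241) fell from 18.1 to 2.09 CPM, Hspb1 (24471) from 52.9 to 9.59 CPM, Adora1 (29290) from 43.8 to 8.58 CPM and Kitlg (60427) from 51.2 to 12.3 CPM. Ptx3 (689388) fell from 19.4 to 3.83 CPM, Thbs2 (292406) from 39.9 to 9.16 CPM and Vgf (29461) from 14.7 to 3.41 CPM. Gda (83585), Olr1 (140914), Mpa2l (305139) and H19 (309122) fell with log2 fold changes of -3.21, -2.31, -2.21 and -2.13. Olr1 was not called without precursor 2 or differentiated 2, Gda and Mpa2l without precursor 2, differentiated 2 or differentiated 5, and H19 without any of these 3 libraries or precursor 5. The edgeR adjusted p without differentiated 2 was 0.0698 for Olr1, 0.107 for Gda, 0.143 for Mpa2l and 0.103 for H19.

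Targets of growth factor and ERK signalling were lower as a list. Of 20, 2 fell over all genes, 7 adjusted over the list alone and 10 with the block, in which 1 rose (median log2 fold change -0.53, camera adjusted p = 0.00186, and 0.202 with an estimated correlation). Spry1 (294981) fell from 8.33 to 3.26 CPM. Etv1 (362733), at -0.64, was the other called gene, and its edgeR adjusted p was 0.102 without differentiated 2, so that 1 member fell there and likewise without precursor 2, precursor 5 or differentiated 5. Spry4 (291610) and Spry2 (306141) had log2 fold changes of -0.81 and -0.53 and passed with the block (edgeR adjusted p = 0.0556 and 0.0582 without it, 0.00612 and 0.0204 with it, lower in 3 of 3 pairs). Of 14 immediate early genes, 2 fell over all genes, while adjusted over the list alone 1 rose and 5 fell, and with the block 1 rose and 6 fell (median -0.38, camera adjusted p = 0.0203, 0.179 with an estimated correlation and 0.0642 with the block). Klf4 (114505) fell from 3.10 to 0.729 CPM, and Btg2 (29619), at -0.79, lost its call without any 1 of the 6 libraries, with an edgeR adjusted p of up to 0.152. The count of members that fell was 1 without precursor 2, precursor 5, differentiated 2 or differentiated 5. Fos (314322) and Jun (24516) had log2 fold changes of -0.77 and 0.39 and passed with the block (edgeR adjusted p = 0.0814 and 0.0702 without it, 0.0102 and 0.00592 with it, each with 3 of 3 pairs in that direction), and Fos had an edgeR adjusted p of 0.00823 without precursor 1.

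The other stress and hormone lists gave weaker or no shifts. Of 21 genes of ER stress and the amino acid response, 3 rose both over all genes and adjusted over the list alone, and with the block 8 rose and 1 fell (median log2 fold change 0.15, and -0.05 on the TPM scale). The list's camera adjusted p was 0.0339, and 0.587 with an estimated correlation, and its call was lost without precursor 2 (0.0726), precursor 5 (0.19) or differentiated 1 (0.0918). Psat1 (293820) rose from 159 to 347 CPM and Vldlr (25696) from 48.9 to 122 CPM. Of 20 p53 targets, 4 fell over all genes and 6 adjusted over the list alone, while with the block 3 rose and 8 fell (median -0.24, camera adjusted p = 0.0579). That list passed without precursor 2 (camera adjusted p = 0.0445), precursor 5 (0.0262) or differentiated 1 (0.0255), yet the number that fell was 2 without precursor 1 and 1 without precursor 2, precursor 5, differentiated 2 or differentiated 5. Plk2 (83722) fell from 40.3 to 22.1 CPM. Of 10 thyroid hormone response genes, 3 rose over all genes, 4 rose and 1 fell adjusted over the list alone, and 4 rose and 2 fell with the block (median 0.31, camera adjusted p = 0.142). It passed without precursor 5 (camera adjusted p = 0.0475) or differentiated 2 (0.0204). Thra (81812) rose from 54.3 to 150 CPM and Hr (60563) from 27.2 to 95.4 CPM, and 0 of the 10 were called without precursor 2 or without differentiated 5. Thra was not called without differentiated 2 either (edgeR adjusted p = 0.0809).

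Of 16 interferon response genes, 0 changed over all genes and 0 adjusted over the list alone by edgeR, with 13 lower with the block and 10 lower without replicate 1. At an unadjusted p under 0.05, 5 of them were lower, and after adjustment 4 with DESeq2, 7 with weighted voom and 5 with limma on the TPM scale. Their median log2 fold change was -0.87 (camera adjusted p = 0.00228, 0.684 with an estimated correlation, and 0.05 without precursor 1, where the call was lost), and 5 fell without differentiated 1. Irf7 (293624) and Ifi44 (310969) had log2 fold changes of -1.77 and -1.04 and passed with the block (edgeR adjusted p = 0.141 and 0.146 without it, 0.000244 and 0.000342 with it, lower in 3 of 3 pairs), and Ifi44 had 0.04 without differentiated 1. The median of the list, as log2 deviation from each gene's mean, was 1.23 in precursor 1 against 0.14 and 0.09 in precursors 2 and 5, and 0.29 in differentiated 1 against -0.84 and -0.96 in differentiated 2 and 5. Microglia and macrophage markers were likewise higher in the replicate 1 libraries, at 0.71 in precursor 1 and 0.50 in differentiated 1 against -0.36 to -0.26 in the other 4. Between the groups, 1 of 20 microglia markers rose over all genes and adjusted over the list alone, and 2 rose and 4 fell with the block (median -0.08, camera adjusted p = 0.945). That gene, C1qc (362634), rose from 6.78 to 13.7 CPM and was not called without precursor 2 (edgeR adjusted p = 0.0758), differentiated 2 or differentiated 5. Aif1 (29427), a microglia marker, was at 72.5 ± 66.8 and 49.0 ± 24.9 CPM (log2 fold change -0.56, edgeR adjusted p = 0.67), and its fold change was 0.50 without precursor 1. Itgam (25021) and Tyrobp (361537) had log2 fold changes of -0.58 and -0.61 and passed with the block (edgeR adjusted p = 0.488 and 0.54 without it, 0.00121 and 0.00664 with it, lower in 3 of 3 pairs), and that of Tyrobp was 0.06 without precursor 1.

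Markers of astrocytes were higher in the same libraries in which the myelin genes were higher. Of 21, 10 rose over all genes, 15 adjusted over the list alone, 17 with the block and 14 without replicate 1 (median log2 fold change 0.80, camera adjusted p = 2.98e-10, and 0.12 with an estimated correlation). Acsbg1 (171410) rose from 130 to 346 CPM, Glul (24957) from 434 to 869 CPM and Aldh1l1 (64392) from 17.4 to 75.3 CPM. Gfap (24387) was at 4072 ± 817 CPM in precursors and 5939 ± 213 CPM in differentiated cells (log2 fold change 0.54, edgeR adjusted p = 0.0849, 0.0138 with the block, higher in 3 of 3 pairs). The astrocyte count was 6 without precursor 5, 3 without differentiated 2 and 6 without differentiated 5. By limma on the TPM scale it was 4, against 13 with DESeq2 and 14 with weighted voom. Of 19 markers of neurons, 4 fell over all genes and 5 adjusted over the list alone, and 7 fell without replicate 1 (median -0.47, camera adjusted p = 0.00541, 0.667 with an estimated correlation and 0.0668 without precursor 5). With the block 1 rose and 6 fell. Gap43 (29423) fell from 321 to 139 CPM and Elavl4 (432358) from 24.9 to 9.33 CPM, and the neuron count was 2 without any 1 library other than precursor 1. In precursor 1 the neuron median was -0.56, against 0.59 and 0.60 in precursors 2 and 5 and -0.35, -0.24 and -0.18 in differentiated 1, 2 and 5.

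**Figure D2:**
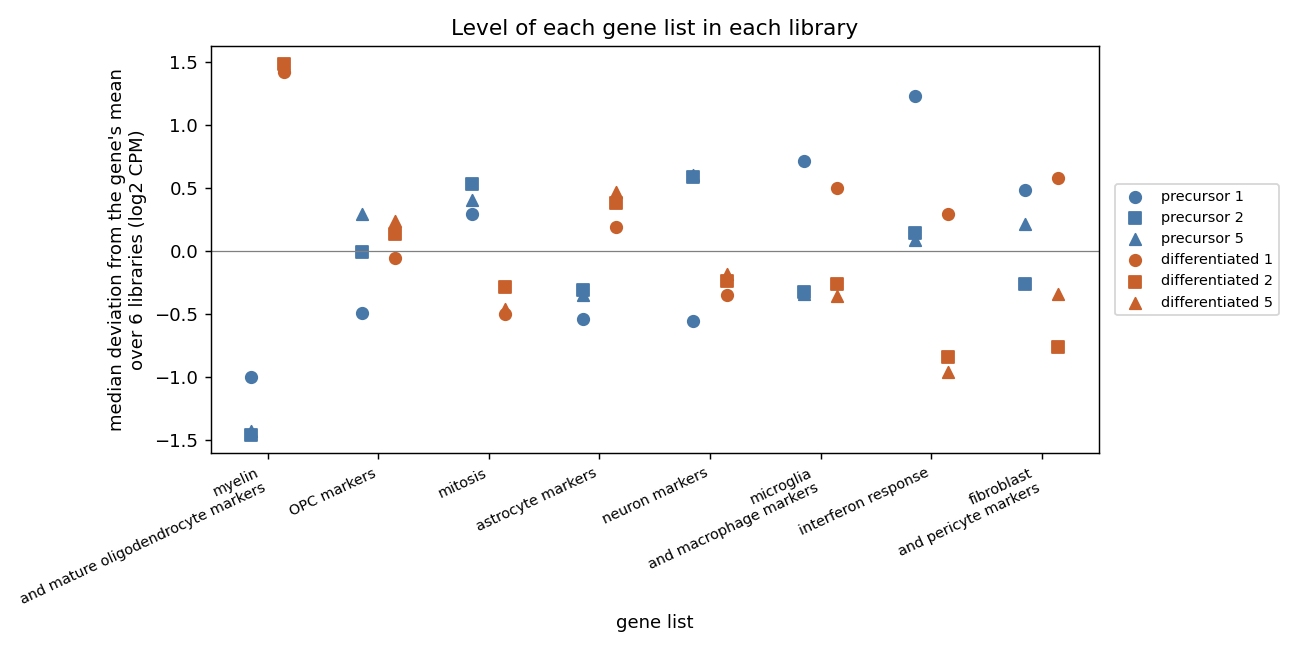
Median deviation of 8 gene lists from each gene's mean over the 6 libraries in log2 CPM, with a point per library (shape gives the replicate, colour the group). Microglia and macrophage markers lay at 0.71 and 0.50 in the replicate 1 libraries and at or below -0.26 in the others, and astrocyte markers lay above 0 in the differentiated libraries alone.

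Markers of other cell types were not called as lists. Of 19 fibroblast and pericyte markers, 4 rose and 1 fell over all genes, 4 rose and 4 fell adjusted over the list alone, and 5 rose and 9 fell with the block (median log2 fold change -0.64, camera adjusted p = 0.945). Tagln (25123) rose from 78.6 to 270 CPM, and without precursor 2 or differentiated 2 only 1 of these markers rose, with 2 without precursor 5, differentiated 1 or differentiated 5. The number that fell was 3 without precursor 1, 2 without differentiated 1 and 0 without the other libraries. Of 14 markers of Schwann, choroid or ependymal cells, 1 rose and 2 fell over all genes, 1 rose and 3 fell adjusted over the list alone, and 3 rose and 5 fell with the block (camera adjusted p = 0.945). That list's median was 0.24, -0.03 on the TPM scale, and its test pointed down. Ttr (24856) fell from 366 to 185 CPM, with an edgeR adjusted p of 0.0257 and of 0.099 without differentiated 5, and lost its call in each leave-one-out fit but that without precursor 1. Cdh19 (360835) rose from 2.05 to 7.22 CPM and lost its call only without precursor 2 (edgeR adjusted p = 0.0527), while the list had 2 higher without precursor 1 and 3 without differentiated 1. The number of these markers that fell was 1 without differentiated 1 or differentiated 2 and 0 without precursor 2, precursor 5 or differentiated 5. Of 10 endothelial markers, 0 were called by edgeR over all genes, adjusted over the list alone or without any 1 library, and 1 rose with the block (median -0.20, camera adjusted p = 0.864). At an unadjusted p under 0.05 and with DESeq2, weighted voom and limma on the TPM scale the endothelial count was also 0.

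Metabolic and translation lists were tested in the same way. Of 22 genes of glycolysis and lactate transport, 4 rose both over all genes and adjusted over the list alone, and 7 rose and 3 fell with the block (median log2 fold change 0.05, negative with library size alone and on the TPM scale). The list's camera adjusted p was 0.06, with 0.043 under the block, 0.0496 without precursor 1, 0.0445 without precursor 2 and 0.0474 without differentiated 5. Eno2 (24334) rose from 34.5 to 137 CPM, and the number that rose was 2 without precursor 2 or differentiated 2 and 1 without precursor 5 or differentiated 5. Of 61 nuclear genes of oxidative phosphorylation, 1 rose over all genes, 0 adjusted over the list alone, and 21 rose and 4 fell with the block (median 0.14, negative with library size alone and on the TPM scale, camera adjusted p = 0.111, with 0.0445 without precursor 2 and 0.0156 without differentiated 5). The number that rose was 0 without precursor 5, differentiated 1, differentiated 2 or differentiated 5. None of the 13 mitochondrially encoded genes was called by edgeR over all genes, adjusted over the list alone or with the block (median -0.50, camera adjusted p = 0.241, with 0.0262 without precursor 5). At an unadjusted p under 0.05, 1 of them was lower, and after adjustment 0 with DESeq2, 0 with weighted voom and 1 on the TPM scale. Of 90 cytosolic ribosomal protein genes, 0 were called over all genes or adjusted over the list alone by edgeR, while with the block 1 rose and 55 fell and without replicate 1, 9 fell (median -0.31, camera adjusted p = 2.02e-05, and 0.687 with an estimated correlation). Rps20 (122772) had a log2 fold change of -0.65 (edgeR adjusted p = 0.097, 0.000964 with the block, lower in 3 of 3 pairs), and 1 member fell without precursor 5 and 1 without differentiated 1. At an unadjusted p under 0.05, 17 ribosomal genes were lower, and after adjustment 5 with DESeq2, 11 with weighted voom and 50 on the TPM scale.

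Receptors and ion channels showed single changes in both directions. Of 26 glutamate and GABA receptor genes, 2 rose and 1 fell both over all genes and adjusted over the list alone, and 4 rose and 1 fell with the block (camera adjusted p = 0.945). That list's median of -0.11 was negative while its test pointed up. Gabrg1 (140674) rose from 41.3 to 84.7 CPM and Grik2 (54257) from 16.7 to 35.1 CPM, and neither was called without precursor 2 or differentiated 2 (edgeR adjusted p of up to 0.124), Gabrg1 without precursor 5 and Grik2 without differentiated 5. Grm5 (24418), at -0.69, lost its call without any 1 of the 6 libraries (edgeR adjusted p of up to 0.154), and 4 members rose without precursor 1. Of 26 genes of ion channels and associated subunits, not all of them voltage-gated, 1 rose and 2 fell both over all genes and adjusted over the list alone, and 3 rose and 3 fell with the block (median -0.03, camera adjusted p = 0.945). Kcnj10 (29718) rose from 10.5 to 30.5 CPM, with an edgeR adjusted p of 0.0272 and of up to 0.111 in the fits without precursor 1, precursor 2, differentiated 2 or differentiated 5, where it was not called, and 2 members rose without differentiated 1. Cacna1g (29717) fell by 1.33 on the log2 scale and was called in 1 leave-one-out fit alone, that without precursor 1, with an edgeR adjusted p of up to 0.122 in the others. The number that fell was 1 without precursor 1 or precursor 5 and 0 without any other single library.

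**Figure D3:**
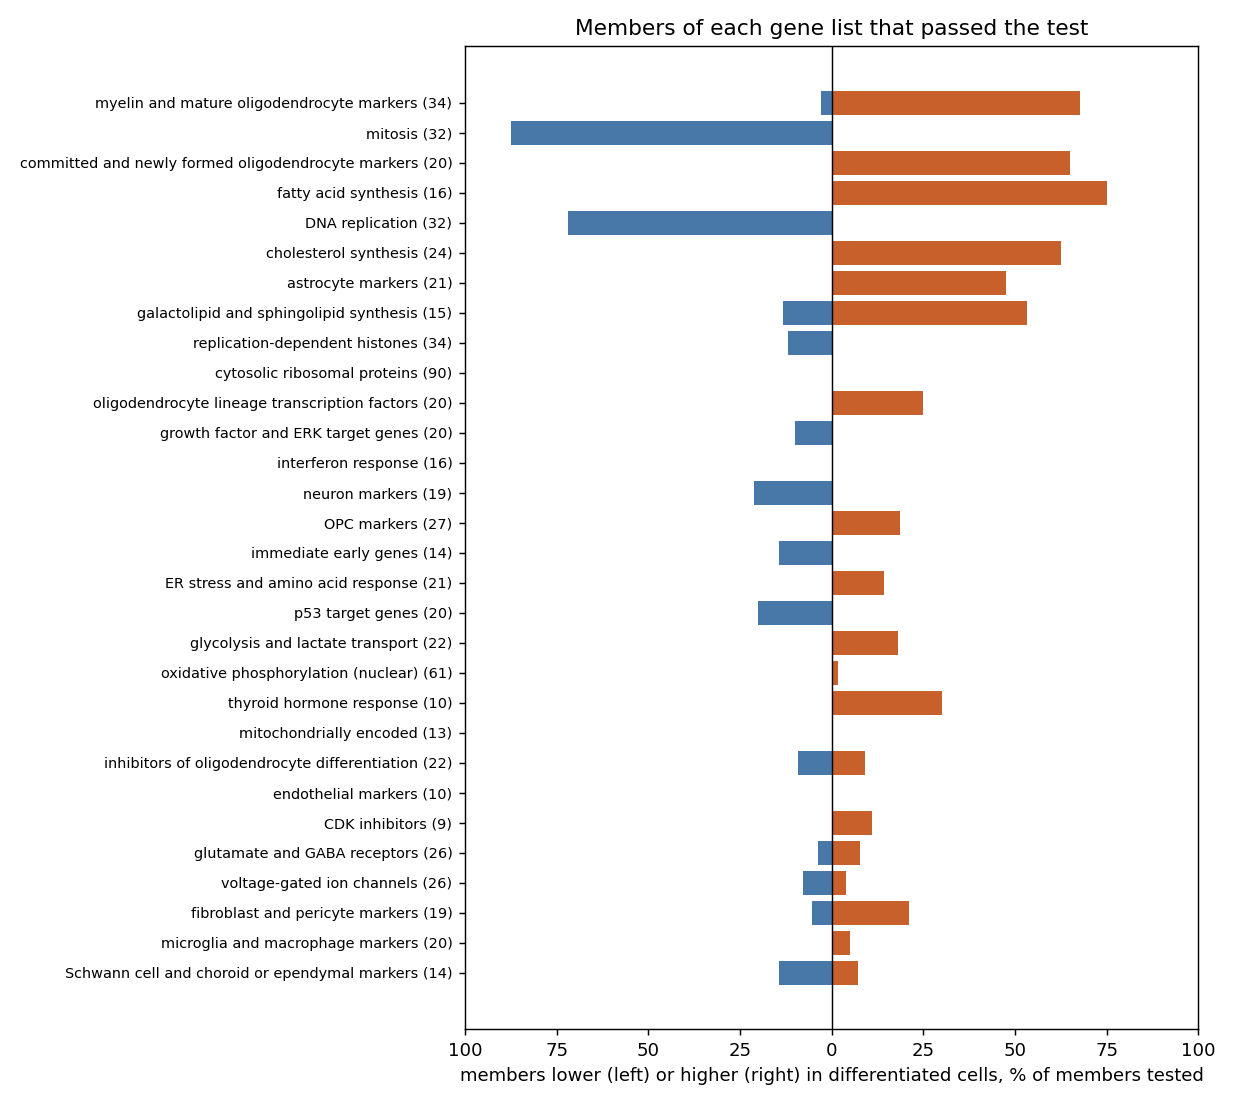
Percent of the tested members of each of the 30 gene lists that passed the test, lower in differentiated cells to the left and higher to the right, with the number tested in brackets. Of the members that passed, those of mitosis (28 of 32) and DNA replication (23 of 32) were lower, and those of fatty acid (12 of 16), cholesterol (15 of 24) and astrocyte lists (10 of 21) were higher.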

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

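The alternatives were chosen before the data were examined, except the fit without both replicate 1 libraries and the list test with an estimated correlation under the replicate block, which were chosen after seeing the data. For changed results the cause was not tested unless one is given. Of 129 named genes followed over 17 settings, 1845 values kept their direction and their side of the threshold, 284 lost the call, 51 gained one and 8 turned in sign. The 5 genes that are among the most abundant had no value in the setting that leaves those out. The 111 called genes among the 129 gave 1883 values, with 4 missing for that reason, and 0 had the opposite sign. The counts kept within 1.5 times under no filter (972 higher, 534 lower), a stricter filter (1057, 627), DESeq2 size factors (965, 596) and with the most abundant genes left out (1022, 582).

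With the replicate block, 2643 genes were higher and 2797 lower, and 603 were at least 2-fold lower. The camera adjusted p of immediate early genes was then 0.0642 and that of glycolysis 0.043, and the ion channel list turned to up at 0.515. The block changed no other list call, and its effect on named genes is given beside them.

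With each library left out in turn, the counts ran from 456 to 911 higher and 162 to 579 lower, and from 394 to 627 and 109 to 338 at least 2-fold. Each of these fits has fewer samples. Camera adjusted p-values ran from 0.000171 to 0.284 for precursor markers, 1.15e-06 to 0.05 for interferon genes, 3.97e-06 to 0.0668 for neuron markers and 0.00467 to 0.19 for ER stress. Of the lists not called, the ranges were 0.0255 to 0.242 for p53 targets, 0.0445 to 0.232 for glycolysis, 0.0156 to 0.532 for oxidative phosphorylation and 0.0204 to 0.413 for thyroid hormone response. Lists that turned direction ran from 0.0262 to 0.862 (mitochondrially encoded genes, turned without precursor 1), 0.244 to 0.971 (inhibitors of differentiation), 0.448 to 0.992 (glutamate and GABA receptors), 0.344 to 0.989 (ion channels), 0.111 to 0.847 (microglia), 0.51 to 0.979 (endothelium), 0.606 to 0.945 (Schwann, choroid and ependymal cells) and 0.408 to 0.979 (fibroblasts and pericytes). The log2 fold changes of genes that turned ran from -1.03 to 0.50 for Aif1, -0.03 to 0.70 for Cspg4, -0.19 to 0.54 for Nkx2-2 and -1.11 to 0.06 for Tyrobp, and that of Nkx2-2 was 0 on the TPM scale.

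In the libraries with a day in their title, 2 against 2, the calls fell to 108 higher and 8 lower, and all of these were at least 2-fold. The camera adjusted p was 0.106 for ER stress, 0.0478 for p53 targets, for thyroid hormone response and for mitochondrially encoded genes, and 0.467 for ion channels, which turned. Without a filter it was 0.0372 for p53 targets and for oxidative phosphorylation, 0.0463 for thyroid hormone response and 0.0179 for glycolysis, while ion channels (0.964) and microglia (0.988) turned. With the stricter filter it was 0.0557 for ER stress.

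With library size as the sole scaling, 1006 genes were lower, 430 at least 2-fold. The camera adjusted p was 0.0741 for ER stress and 0.0398 for p53 targets, and the lists of kinase inhibitors and endothelium (both 0.978), ion channels, fibroblasts and Schwann or choroid cells (each 0.877) and microglia (0.964) turned. On log2(TPM + 1), 487 genes were higher, 316 of them at least 2-fold, and 1000 lower. There the list p was 0.173 for ER stress and 0.159 for neurons, and kinase inhibitors, fibroblasts and Schwann or choroid cells (each 0.575), ion channels (0.443), endothelium (0.731) and oxidative phosphorylation (0.722) turned. Both settings shift the median log2 fold change over all tested genes, to -0.188 and -0.172.

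The DESeq2 Wald test called 1521 genes higher and 1252 lower, 463 at least 2-fold, with a list p of 0.0453 for p53 targets, and glutamate receptors (0.991) and fibroblasts (0.988) turned. Voom with sample weights called 1860 and 1763, 667 at least 2-fold lower. Its camera adjusted p was 0.176 for precursor markers and 0.0176 for oxidative phosphorylation, and microglia and Schwann or choroid cells (both 0.833) and mitochondrially encoded genes (0.993) turned. It gave the replicate 1 libraries the lowest weights, 0.35 and 0.42, against 1.04 to 2.67. Without both replicate 1 libraries, 1546 genes were higher and 1475 lower, 568 at least 2-fold. Precursor markers then had 0.0758, Schwann or choroid cells (0.81) and mitochondrially encoded genes (0.769) turned, and the log2 fold change of Aif1 was 0.05.

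With an estimated correlation between genes, the lists of myelin, cholesterol and galactolipid genes kept their calls and 14 lost them. The camera adjusted p was 0.0642 for committed oligodendrocytes, fatty acids and mitosis, 0.112 for DNA replication, 0.12 for astrocytes, 0.179 for immediate early genes, 0.202 for growth factor targets, 0.413 for transcription factors, 0.429 for histones, 0.587 for ER stress, 0.667 for neurons, 0.684 for interferon, 0.687 for ribosomal proteins and 0.716 for precursor markers. Under the replicate block it called none of the 30 lists. It was then 0.0992 for committed oligodendrocytes, cholesterol, mitosis and astrocytes, 0.141 for galactolipids, 0.15 for myelin, transcription factors, DNA replication and interferon, 0.178 for growth factor targets and ribosomal proteins, 0.241 for fatty acids, 0.344 for immediate early genes, 0.581 for ER stress and histones and 0.709 for precursor and neuron markers, and ion channels turned at 0.825. These values rest on few residual degrees of freedom.

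Alternatives on the pseudocount and on sums per symbol were not run, since counts were tested and entries are genes already. The smallest library held 55.5 reads per CPM, so genes near 1 CPM rest on few reads, and 22% of simulated genes with a 2-fold change were called at this number of libraries.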

Other observations

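The tests of the replicate block in other splits, of depth (of precursor 1, and of both replicate 1 libraries by thinning), of a lower share of lineage cells and of the astrocyte share were chosen only after the result was seen. The 3 further gene lists tested here were prompted by genes seen in the results, but were fixed before the values of their members were seen.

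Of the 10 ways to part the 6 libraries into 3 and 3, 1 split reached the 1576 genes called between the groups, the real one, and the highest count of another split was 0. With the replicate block, edgeR called 5440 genes in the real split and 0 in each of the 3 other splits that part each same-numbered pair, where 21, 20 and 95 genes had an unadjusted p under 0.05. In these splits the difference between the groups adds to the spread, so that low counts say little. With 10 splits, no share under 0.05 can be reached.

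Both replicate 1 libraries stood apart from replicates 2 and 5 in the same way: of all tested genes, 27.6% were higher and 24.4% lower in replicate 1 than in both other replicates in both groups. Chance gives 11.1% if the order of replicates is independent between the groups. Same-numbered libraries deviated together for each number, and these shares were not computed for replicates 2 and 5. A second list of 26 macrophage genes was higher in replicate 1 by a median of 1.32 on the log2 scale in precursors and 0.99 in differentiated cells, and 25 of the 26 were higher in both groups, so a larger share of microglia or macrophages may account for part of the pattern. Of the first list of 20 microglia markers, 18 were higher in both groups. Among its abundant members, Csf1r (307403) had 221 CPM in differentiated 1 against 133 and 155 CPM in differentiated 2 and 5. Cx3cr1 (171056) was lower in precursor 1, at 4.90 against 8.23 and 9.24 CPM in precursors 2 and 5. Spp1 (25353), which is not on that list, had 7937 CPM in precursor 1 against 4097 and 3505 CPM. Csf1r, Cx3cr1 and Spp1 are named outside the rule. A smaller share of lineage cells with every other cell type alike would raise both lists alike, if lineage cells do not express the astrocyte genes. The microglia median of replicate 1 lay above the astrocyte median by 1.61 in precursors and 1.13 in differentiated cells. This was beyond the spread over genes, the sole spread that 1 library against 2 gives. Of 21 astrocyte markers, 12 were lower in replicate 1 in both groups and 3 higher. These values argue against that share only under this condition, which was not tested, so they cannot decide the question. Of 27 precursor markers, 15 were lower in replicate 1 in both groups and 1 higher, while of 34 myelin markers 5 were lower and 11 higher. By the same count, 64 of 90 ribosomal protein entries were higher and 5 lower, and 15 of 16 interferon genes were higher. Among 19 fibroblast and pericyte markers, 9 were higher and 4 lower. Rn7sl1 took 9.98% of counts in precursor 1 against 7.88% and 5.93% in precursors 2 and 5. It took 12.5% in differentiated 1 against 10.3% and 9.55% in differentiated 2 and 5. Whether these differences share a cause with those of the macrophage genes was not tested. Depth is argued against, since with all libraries thinned to the smallest total 27.5% of genes were still higher and 24.5% lower in replicate 1 in both groups, although differentiated 1 had the highest total of its group (79898629 counts), while that of precursor 1 was at rank 2 of 3.

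The astrocyte markers rose by different amounts. If a larger share of astrocytes alone were the cause, and other cells did not express these genes, each marker would rise by about the list's median. In the blocked fit, 71.4% of the 21 markers lay more than 2 SE from that median, among them Aldh1l1 (64392) at 2.13 and Slc1a2 (29482) at -0.28 against a median of 0.79. This argues against a larger share as the sole cause only if other cells do not express these genes, which was not tested. Changed expression within astrocytes, and expression of some of these genes by oligodendrocyte lineage cells, remain open and may act together with a changed share.

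More genes were lower than higher on the TPM scale, with a median log2 fold change of -0.172. With Rn7sl1 and Rmrp left out and TPM scaled again, the median was -0.027, and 864 genes were higher and 506 lower in place of 487 and 1000. The share of these small RNAs in the total is thus a candidate explanation for the excess of lower genes on that scale.

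Among genes chosen after their values were seen, Pnlip (25702), a lipase gene, rose from 94.4 ± 9.2 to 961 ± 144 CPM, Apoe (25728) from 1110 ± 102 to 3822 ± 64.2 CPM and Dgat2 (252900) from 31.8 to 182 CPM. Genes of cytokine signalling were among the lower ones, with log2 fold changes of -4.02 for Serpina3n (24795), -3.12 for Lif (60584), -1.72 for Socs3 (89829) and -1.40 for Osmr (310132), as were the matrix genes Col4a1 (290905, -1.46), Lamb1 (298941, -1.37) and Has2 (25694, -1.70).

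It was therefore tested whether further genes of the STAT3 pathway and acute phase, and of basement membrane, moved as groups, with the genes already seen left out. Of 28 STAT3 and acute phase genes, 4 fell and 1 rose. Their median log2 fold change was -0.57, and the camera adjusted p of limma over the 3 lists was 0.00346 (0.00115 before adjustment). Before adjustment the value was 0.173 with an estimated correlation and 1.46e-05 with the replicate block, where 16 members fell and 1 rose. Of 21 basement membrane genes, 5 fell and 0 rose, with a median of -0.51 (camera adjusted p = 0.0117, 0.00778 before adjustment, 0.124 with an estimated correlation and 0.0108 with the replicate block). With the block 9 of these genes fell and 3 rose. Both groups may be lower in differentiated cells, a hypothesis that the tests with an estimated correlation leave open. The themes were picked because related genes fell in the same 6 libraries. Genes regulated together share such a fall, so these tests are not independent of what prompted them. The adjustment over 3 lists does not cover that choice. The second macrophage list had a camera adjusted p of 0.173 between the groups, with a median of -0.31, while with the replicate block the value before adjustment was 0.000376, with 12 of 26 members lower and 3 higher.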
